A study of Naumovozyma castellii with 10 samples.

How the data were processed

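Small RNA sequencing was carried out on 10 libraries of the budding yeast Naumovozyma castellii, in 5 groups of 2 that the labels describe as biological replicates. The groups were wild type (WT), a mutant lacking the nonsense-mediated decay helicase Upf1 (upf1), the same mutation without the RNase III enzyme Dicer (dcr1 upf1), wild type treated with the translation inhibitor cycloheximide (WT CHX) and a Dicer mutant treated in the same way (dcr1 CHX). Per the labels' protocols, cells were grown in rich medium at 25 °C to an OD600 of 0.5, and cycloheximide was given at 100 µg/mL for 15 min. RNA came from a hot phenol extraction, and 25 µg of it was mixed with 1 µg of Schizosaccharomyces pombe total RNA. The 22 to 23 nt centromeric small RNAs of S. pombe served as the spike-in. RNA below 80 nt was purified on 15% gels, and 50 to 100 ng of it entered a ligation-based library kit.

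The deposited values are a coverage signal, namely a normalised density of reads per nucleotide of each annotated feature, scaled by the authors to the S. pombe spike-in per the labels' protocols. The submitters' processing notes name Trim Galore, Bowtie and the S. pombe build ASM294v2, without versions. The N. castellii build, the annotation version, the range of read lengths counted and the treatment of reads that map to several places are not given in the sources used here. Multiplied by feature length, the densities of each library were whole multiples of a single step for 100% of the 8770 annotation entries, within a tolerance of 0.001 reads, so whole reads and library factors were recovered. The factor was 1 in WT CHX replicate 1, whose densities are therefore plain reads per nucleotide. The file also held 5 group means, which were not used.

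Of the 8770 entries, 92 were synthetic control sequences with 0 reads, and 271 repeated the interval and strand of another entry, among them 259 tRNA entries, 2 rRNA entries and 10 entries named DUT that lie at XUT intervals. The remaining 8407 features comprised 5600 mRNAs, 1021 XUTs (transcripts sensitive to the exonuclease Xrn1), 1280 CUTs (cryptic unstable transcripts), 146 SUTs (stable unannotated transcripts), 304 tRNAs, 37 snoRNAs and 12 rRNAs. XUTs, CUTs and SUTs are long non-coding RNAs (lncRNAs). The lengths of 97.6% of the mRNAs were multiples of 3, so mRNA intervals are coding lengths. Coordinates are those of the deposited file. In the reference gene table of assembly ASM23734v1, 5589 mRNA identifiers were found, with the same start for 5589 and the same end for 5587. That table gave gene symbols for 4484 mRNAs. UPF1 is listed there as NAM7, and DCR1 and AGO1 are not named there. A same-strand interval was shared by 774 features, mostly XUT and CUT annotations of the same transcript (393 lncRNA pairs), and their values are not independent.

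The main test was limma 3.58.1 in R 4.3.3 on log2(density + 0.00148), with a group-means model, moderated variances with a trend, and Benjamini-Hochberg adjustment over the features tested. Calls were two-sided at an adjusted p of 0.05. The pseudocount is the median over libraries of the 10th percentile of non-zero densities, and features with a mean below it were not tested. Fold changes are on this log2(density + pseudocount) scale, which understates changes of sparse features. The 6 Dicer-proficient libraries were fitted together for the upf1 and CHX comparisons, and all 10 libraries for the Dicer comparisons and their interaction. Class totals were sums of density per library, compared by an exact two-sided permutation test that cannot go below p = 0.333 with 2 against 2. Lists were tested with camera from limma at a preset correlation of 0.01, and again with an estimated correlation. Camera compares the moderated t-statistics of a list, not its fold changes, with those of all other tested features. All of these choices, the lists and most of the alternative settings were set before the data were examined.

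The lists were the feature classes XUT, CUT, SUT, mRNA, tRNA and snoRNA; mRNAs antisense to a lncRNA, antisense to another mRNA only, or with no antisense feature; XUTs with the DUT annotation; and genes for NMD factors, RNA decay, cytosolic ribosomal proteins, translation factors, histones, glycolysis and heat shock. Gene lists were matched by symbol pattern, which took RPP1, GCD10 and GCD14 into the ribosomal protein and translation factor lists. An RNAi list (DCR1 and AGO1) and the members NOT1 and TEF1 had no match, and a transposon list was not tested. Named features were chosen by rule. They are the 8 largest rises and 8 largest falls per comparison among called features with separated replicates and a higher group mean at or above the median, the 5 lncRNAs and 5 mRNAs with the highest density, UPF1, DCR1 and AGO1, and called members of the gene lists. Of features without a symbol, at most 2 that rose and 2 that fell were named per comparison.

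The procedure was tested on simulated data, in which 200 features were changed by 2-fold or 4-fold in 20 simulations per comparison. Every simulated library was drawn from the mean of a single group. That group was WT for the comparisons with WT, and upf1 for WT CHX against upf1 and for the interaction. For the interaction this gave the simulated Dicer-deficient libraries the density of upf1, far above that in the data. Its recovery and false calls therefore do not carry over to the interaction as measured. For the Dicer comparisons it was the Dicer-deficient group, which left 2575 and 4377 features tested on average, against 7704 in the data. Far fewer features were changed than were called in the data, so recovery and false calls there may differ. Of 4-fold rises the procedure recovered 48.7% for upf1 against WT, 51.9% for WT CHX against WT, 80.9% for WT CHX against upf1, 25.3% for dcr1 upf1 against upf1, 11.5% for dcr1 CHX against WT CHX and 63.3% for the interaction. Of 4-fold falls it recovered 25.5%, 27.7%, 57.3%, 14.1%, 5.9% and 50.3%, in the same order. Of 2-fold rises it recovered 6.2% for upf1 against WT and 8.1% for WT CHX against WT. False calls made up 9.73% of calls for upf1 against WT, 11.2% for WT CHX against WT, 9.58% for WT CHX against upf1, 7.51% and 21.8% for the Dicer comparisons in upf1 and CHX cells, and 7.15% for the interaction, above the nominal level. For pairs of an mRNA and its antisense lncRNA, random pairs were drawn 100000 times within deciles of lncRNA density, without matching the density of the mRNA. Effects shared through the WT controls were gauged with 100 simulations.

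The settings chosen beforehand changed the pseudocount, the filter, the scaling, the libraries in the fit, the variance model, the size threshold and the replicate block, and left out each library in turn. The scaling was replaced by the mRNA median, called mRNA-median scaling below, or by the sum of tRNA, rRNA and snoRNA. A count-based test (limma voom on the recovered reads), a fit with every annotation entry, a fit without features that share an interval, and a repeat of the analysis of reads left without Dicer on features that do not overlap, were added after seeing the data. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Where a group had 0 reads, the bound uses a floor of 3 reads over the 2 libraries of the group together, and the pooled reads of the other group. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.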

Results

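Small RNAs were sequenced from N. castellii, a budding yeast that has kept RNA interference, to ask which small RNAs appear when nonsense-mediated decay (NMD) is impaired, either by loss of UPF1 or by blocking translation with cycloheximide (CHX), and which of them need Dicer. Each of the 5 groups had 2 libraries. Over all features, the WT libraries held 4144522 and 3389205 reads, upf1 6237106 and 6904640, and WT CHX 3169072 and 4323102. The Dicer-deficient libraries held far fewer reads over these features, 129559 and 141701 in dcr1 upf1 and 137085 and 148330 in dcr1 CHX. These counts are not library sizes. The recovered library factors, which scale reads to the spike-in, were 0.349 and 0.349 in dcr1 upf1 and 0.529 and 0.494 in dcr1 CHX. They were 0.485 and 0.572 in WT, so the lower counts do not show shallower sequencing. A single transcript, XUT0769, took 12.7% to 17.2% of the reads of each Dicer-proficient library, and the 10 features with the most reads took 46.4% to 67.1%. Replicates correlated across features with Pearson r between 0.899 and 0.965. The leading principal component, with 86.6% of the variance, ran from upf1 and WT CHX through WT to the Dicer-deficient libraries, and the next, with 5.65%, separated upf1 from WT CHX.

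The UPF1 gene itself (NAM7, chromosome 1, 1536668 to 1539646, minus strand) had 0 reads in all 4 libraries that lack it. It had 13 and 3 reads in WT, 21 and 45 in WT CHX, and 4 and 8 in dcr1 CHX. Counting 3 reads over both upf1 libraries as the floor, its density was at least 3.91-fold lower in upf1 than in WT, which did not pass the test (limma adjusted p = 0.151), and it rose with CHX by a log2 of 1.85 (SE 0.47, limma adjusted p = 0.00973). DCR1 is not named in the gene table, so its deletion could not be checked at the locus.

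Summed density showed how small RNA output moved by class. XUT density was 771 ± 15.7 in WT, 1669 ± 19.4 in upf1 and 1093 ± 85.6 in WT CHX (SD, n = 2 each), ratios to WT of 2.16 ± 0.0413 and 1.42 ± 0.0937 (SD over pairs of replicates). CUT density rose to 3.11 ± 0.0970 times WT in upf1 and 1.77 ± 0.144 times with CHX, SUT density to 2.79 ± 0.0782 and 1.84 ± 0.162 times, and density on mRNA strands to 2.48 ± 0.122 and 1.70 ± 0.147 times. The sums for snoRNA, 1.28 ± 0.118 and 1.36 ± 0.0850 times WT, and tRNA, 1.23 ± 0.113 and 1.33 ± 0.0847 times, moved less. Without Dicer the lncRNA classes nearly vanished. XUT density in dcr1 upf1 was 0.158% of upf1 and in dcr1 CHX 0.435% of WT CHX, CUT density 0.188% and 0.764%, SUT density 2.02% and 3.63%, and mRNA-strand density 1.82% and 3.97%, while tRNA density was 128% and 143%. Direction and size depended on the summary. As the median over features, the ratio of upf1 to WT was 5.61 for XUTs, 3.98 for CUTs, 1.83 for SUTs and 0.990 for tRNAs. That of WT CHX to WT was 3.36 for XUTs, 3.42 for CUTs, 3.24 for SUTs, 3.92 for mRNAs, 1.95 for snoRNAs and 2.003 for tRNAs, and that of dcr1 upf1 to upf1 0.852 for tRNAs. All of the ratios of sums separated the replicates completely, and each had an exact two-sided permutation p = 0.333, the lowest that 2 against 2 allows.

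**Figure D1:**
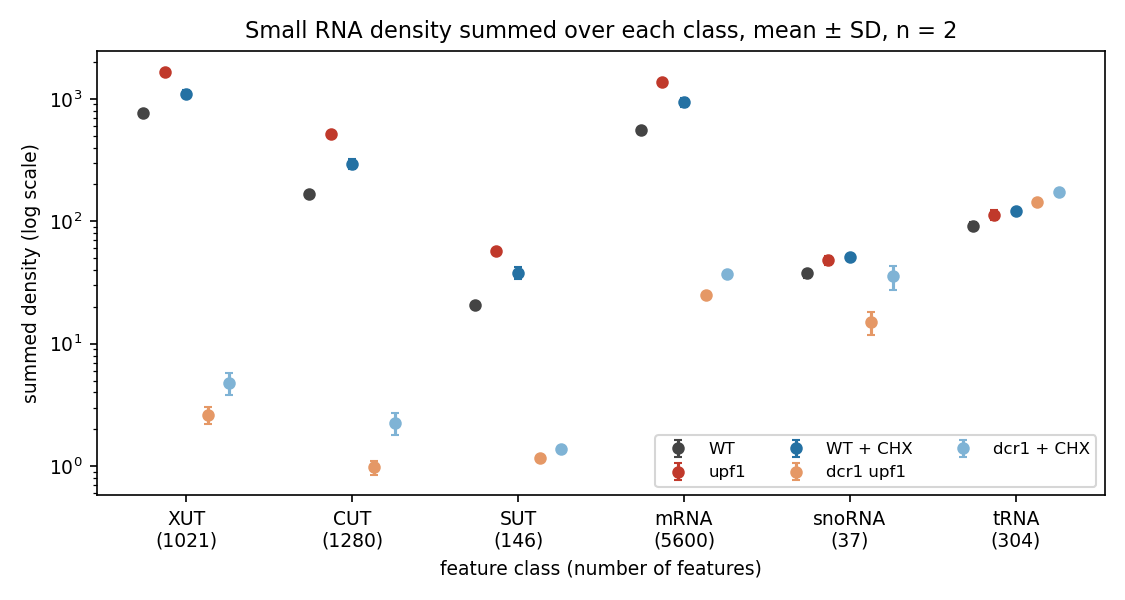
Summed spike-in-normalised density (log scale) of each feature class in the 5 groups, as mean with SD over 2 libraries. XUT density runs from 771 in WT to 1669 in upf1 and 2.63 in dcr1 upf1, while tRNA density stays between 91.6 and 174 in all groups.

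Loss of UPF1 raised small RNAs over most tested features, and the median feature rose most among XUTs, although their summed density over all features rose least of the lncRNA and mRNA classes. That order of the sums rested on the 10 densest features. Without them the XUT sum was 2.83 times WT, with SUTs unchanged at 2.79 times. 748 of 950 tested XUTs were higher in upf1 than in WT, with a median log2 fold change of 2.15, as were 749 of 1143 CUTs (median 1.69) and 2934 of 5361 mRNAs (median 1.06). XUT0058 (chromosome 1, 601672 to 603421, minus strand), antisense to the mRNA NCAS_0A03060, rose 155-fold, from a density of 0.0476 ± 0.00150 to 7.58 ± 0.227 (log2 7.27, SE 0.13, limma adjusted p = 5.67e-07). The opposite strand, NCAS_0A03060 (601736 to 603250), rose with it by a log2 of 7.01 (SE 0.14). The densest lncRNAs changed far less: XUT0859 on chromosome 8 rose 3.39-fold and XUT0620 on chromosome 5 1.75-fold.

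Over all 7872 tested features, 4549 were higher in upf1 and 50 lower, and the median log2 fold change was 1.19. With mRNA-median scaling, which takes that shift out, 2114 were higher and 1026 lower. The XUT list stood above the other features (camera adjusted p = 1.08e-08, and adjusted p = 0.433 with an estimated correlation). CUTs did not (camera adjusted p = 0.0848), except with a pseudocount 10 times larger (camera adjusted p = 0.0387). SUTs, with 69 of 133 higher, had a median of 0.93, or -0.30 with mRNA-median scaling. When adjusted over the list alone, 763 XUTs, 759 CUTs and 68 SUTs were higher. Of the 10 XUTs with the DUT annotation 7 rose, also adjusted over the list alone, with a median of 0.79, or -0.44 with mRNA-median scaling.

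Among the largest rises were XUT0341 on chromosome 2 (801611 to 802216), with a log2 of 7.22 (SE 0.33), and CUT0642 on chromosome 3, with 7.13 (SE 0.19). CUT1109 on chromosome 8 (9256 to 10139) rose by a log2 of 7.07 (SE 0.26) and CUT0912 on chromosome 6 (3941 to 4686) by 7.05 (SE 0.19). CUT0504, antisense to the bud-site gene AXL2, rose 128-fold. Among the features that passed the rule for naming, the largest change was in the mRNA NCAS_0J00110 (chromosome 10, 2167 to 3219), at a log2 of 7.41 (SE 0.33), from 8 reads in WT to 1736 in upf1. Among the few features that fell were the snoRNA ENSRNA049639776 on chromosome 1, from a density of 1.47 ± 0.160 to 0.383 ± 0.104 (log2 -1.95, SE 0.21), the snoRNA ENSRNA049639788 (log2 -3.01, SE 0.57) and SUT138 on chromosome 9 (log2 -1.59, SE 0.20).

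An mRNA with an annotated lncRNA on its opposite strand rose more often. Of 1257 such mRNAs 888 were higher (median 1.55; camera adjusted p = 0.000966, and adjusted p = 0.619 with an estimated correlation), and of 4088 without any antisense feature 2033 were higher (median 0.94, or -0.29 with mRNA-median scaling; camera adjusted p = 0.000475 for a smaller change than the rest, and adjusted p = 0.503 with an estimated correlation). Of 16 mRNAs antisense to another mRNA only, 13 rose, with a median of 2.05 (camera adjusted p = 0.0282, and adjusted p = 0.396 with an estimated correlation). These counts, adjusted over the list alone, were 912, 1965 and 14, and that for all mRNAs was 2897. In 1062 of 1605 pairs of an mRNA and its antisense lncRNA both strands were called higher. That is 66.2% of pairs, against 60.2% on average and 61.9% at most in pairs redrawn at random within deciles of lncRNA density (permutation p = 1e-05, the smallest that 100000 draws can give). The density of the mRNA was not matched, and overlapping XUT and CUT annotations can enter as separate pairs with the same mRNA. This p-value may therefore be too small. The Spearman correlation of fold changes across pairs was 0.808, and pairs are not independent replicates.

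The share of genes that rose varied between the gene lists. Of 10 heat shock genes 8 rose (median 1.87), and 9 adjusted over the list alone. HSP104, a protein disaggregase, rose by a log2 of 2.66 (SE 0.48), HSP10, a mitochondrial chaperonin, by 2.53 (SE 0.21) and the Hsp70 gene SSA3 by 2.51 (SE 0.31). Of 22 RNA decay genes 11 rose (median 0.70, or -0.52 with mRNA-median scaling), led by SKI7, which links the Ski complex to the exosome (log2 3.03, SE 0.25), the decapping enhancer EDC3 (2.38, SE 0.23) and LSM6, of the Lsm ring that binds RNA ends (2.33, SE 0.18). Of 22 translation factors 8 rose (median 0.64, or -0.58 with mRNA-median scaling), among them GCD7, a subunit of eIF2B (log2 2.40, SE 0.28), and SUI1, eIF1 (3.99-fold). Of 108 ribosomal protein genes 57 rose (median 0.79, or -0.43 with mRNA-median scaling), the highest being RPL28 (log2 2.49, SE 0.18). Of 14 glycolysis genes 8 rose (median 1.04, or -0.18 with mRNA-median scaling), with PGK1 at a log2 of 1.77 (SE 0.22) and TDH2 at 1.59 (SE 0.23). Only HTZ1, the variant histone H2A.Z, rose among 8 histone genes (log2 2.19, SE 0.31; median of the list 0.36, or -0.87 with mRNA-median scaling). Of the 3 NMD factor genes UPF3 (log2 2.19, SE 0.32) and NMD2 (1.42, SE 0.24) rose. For RNA decay, translation factors, ribosomal proteins, glycolysis, histones and NMD factors the counts adjusted over the list alone were the same, and camera called no gene list, with histones nearest (camera adjusted p = 0.0612).

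The tRNAs and snoRNAs stayed behind this rise. Of 241 tRNAs 33 were higher and 11 lower (18 and 4 adjusted over the list alone), with a median log2 fold change of 0.00, or -1.22 with mRNA-median scaling (camera adjusted p = 1.61e-26, and adjusted p = 0.00465 with an estimated correlation). An exact 0 can come from features without reads in either group, and summed tRNA density was 1.23 times WT, so this median does not show a lack of change. The tRNA list was the only list of this comparison whose call held with an estimated correlation. Of 37 snoRNAs 16 were higher and 6 lower, also adjusted over the list alone, with a median of 0.49, or -0.73 with mRNA-median scaling (camera adjusted p = 0.000501, and adjusted p = 0.175 with an estimated correlation). With mRNA-median scaling XUT0620 turned negative, at -0.41, and SUI1, HSP104, PGK1, TDH2, HTZ1 and NMD2 lost their calls, and NAM7 passed the test with that scaling, with the smaller pseudocount and by read counts.

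Cycloheximide for 15 min raised small RNAs even more broadly, and the median mRNA rose at least as much as the median lncRNA. The summed densities did not separate mRNAs (1.70 ± 0.147 times WT) from CUTs (1.77 ± 0.144) and SUTs (1.84 ± 0.162). Without the 10 densest features the sum of mRNAs (2.502 times WT) lay above that of CUTs (2.04). 4363 of 5361 mRNAs were higher in WT CHX than in WT (median log2 fold change 1.57), as were 734 of 950 XUTs (1.41), 794 of 1143 CUTs (1.38) and 100 of 133 SUTs (1.37). NSA2, needed for large ribosomal subunit assembly, rose 32.8-fold (log2 5.04, SE 0.26, limma adjusted p = 6.53e-05), from a density of 0.00574 ± 0.00114 to 0.234 ± 0.00406 (SD, n = 2 each). GLO3, a GTPase-activating protein of Golgi transport, rose by a log2 of 5.03 (SE 0.21) and the biotin transporter VHT1 by 4.99 (SE 0.24). XUT0035, antisense to the agglutinin gene AGA2, rose by 5.19 (SE 0.60), from 4 reads to 138, and the mRNA NCAS_0E02010 on chromosome 5 by 6.01 (SE 0.38), from 4 reads to 360.

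In total 6070 of 7872 features were higher with CHX and 13 lower, with a median log2 fold change of 1.502. With mRNA-median scaling the split turned to 722 higher and 1215 lower, and the medians of mRNAs, XUTs, CUTs and SUTs were then -0.18, -0.34, -0.37 and -0.38. Adjusted over the list alone, 4396 mRNAs, 734 XUTs, 779 CUTs and 100 SUTs were higher. The mRNA list stood above other features (camera adjusted p = 0.0107, and adjusted p = 0.699 with an estimated correlation) and the XUT list did not (camera adjusted p = 0.540). The number of features lower was 23 and 35 without WT replicates 1 and 2, and 22 and 27 without WT CHX replicates 1 and 2. A mitochondrial tRNA, tRNA-17279, fell by a log2 of 0.57 (SE 0.10, limma adjusted p = 0.0017), a call that ended when all 10 libraries were fitted.

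Most members of each gene list rose with CHX, as did most mRNAs, and camera called only glycolysis and the ribosomal proteins upwards among the gene lists. That call rests on t-statistics, and the median rise of the ribosomal proteins (1.54) was not above that of all mRNAs (1.57). All 14 glycolysis genes were higher (median 1.97; camera adjusted p = 0.0141, and adjusted p = 0.699 with an estimated correlation), among them the hexokinase HXK2 (log2 2.83, SE 0.47), the phosphofructokinase PFK2 (2.57, SE 0.29) and PGK1 (2.42, SE 0.22). Of 108 ribosomal protein genes 100 rose (median 1.54, or -0.21 with mRNA-median scaling; camera adjusted p = 0.0287, and adjusted p = 0.699 with an estimated correlation), with RPS15 at 2.75 (SE 0.24) and RPS7A at 2.67 (SE 0.19). Of 22 translation factors 21 rose (median 1.89), led by the eIF4G gene TIF4632 (log2 3.68, SE 0.53), the eIF3 subunit TIF34 (3.13, SE 0.40) and the eIF4A gene TIF1 (2.63, SE 0.26). Of 22 RNA decay genes 17 rose (median 1.59, or -0.16 with mRNA-median scaling). DHH1, a helicase that promotes decapping, rose 17.0-fold (log2 4.09, SE 0.33), EDC3 by 2.63 (SE 0.23), SKI7 by 2.62 (SE 0.25) and the exonuclease gene XRN1 by 2.45 (SE 0.38). Of 10 heat shock genes 9 rose (median 1.87), including SSA3 (3.42, SE 0.31) and HSP60 (2.34, SE 0.30). Of 8 histone genes 6 rose (median 1.74, or -0.01 with mRNA-median scaling), including HHF1, histone H4 (2.98, SE 0.58), and HTZ1 (2.72, SE 0.31). All 3 NMD factor genes rose, with UPF3 at 2.13 (SE 0.32) and NMD2 at 2.01 (SE 0.24). Adjusted over the list alone, the counts were 14 for glycolysis, 101 for ribosomal proteins, 22 for translation factors, 18 for RNA decay, 9 for heat shock, 6 for histones and 3 for NMD factors.

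The densest lncRNAs again moved little, with CUT1261 on chromosome 9 at 1.47-fold and XUT0859 at 1.42-fold, and of the 10 XUTs with the DUT annotation 5 rose (median 0.35, or -1.40 with mRNA-median scaling). Of mRNAs antisense to a lncRNA 1056 of 1257 rose (median 1.51, or -0.24 with mRNA-median scaling; camera adjusted p = 0.0107, and adjusted p = 0.699 with an estimated correlation), of those antisense to another mRNA only all 16 (median 1.69, or -0.06), and of those with no antisense feature 3291 of 4088 (median 1.59, or -0.16). The same counts adjusted over the list alone were 5, 1067, 16 and 3312. Of 241 tRNAs 58 were higher (45 adjusted over the list alone), with a median of 0.62, or -1.13 with mRNA-median scaling (camera adjusted p = 1.74e-38 for a smaller change than the rest, and adjusted p = 0.00263 with an estimated correlation, the only list to hold). Of 37 snoRNAs 19 were higher (12 adjusted over the list alone), with a median of 0.53, or -1.22 with mRNA-median scaling (camera adjusted p = 4.92e-05, and adjusted p = 0.112 with an estimated correlation). Of 1605 sense and antisense pairs 1178 had both strands higher, 73.4% against 71.2% in pairs redrawn in the same way, with the same limits (permutation p = 1e-05, the smallest possible). CUT1261 (-1.19) and XUT0859 (-1.24) turned negative with mRNA-median scaling and lost their calls with scaling on tRNA, rRNA and snoRNA. PGK1, UPF3, XRN1, HTZ1, PFK2, HXK2, HHF1, HSP60 and NMD2 kept a positive value with mRNA-median scaling without passing the test.

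**Figure D2:**
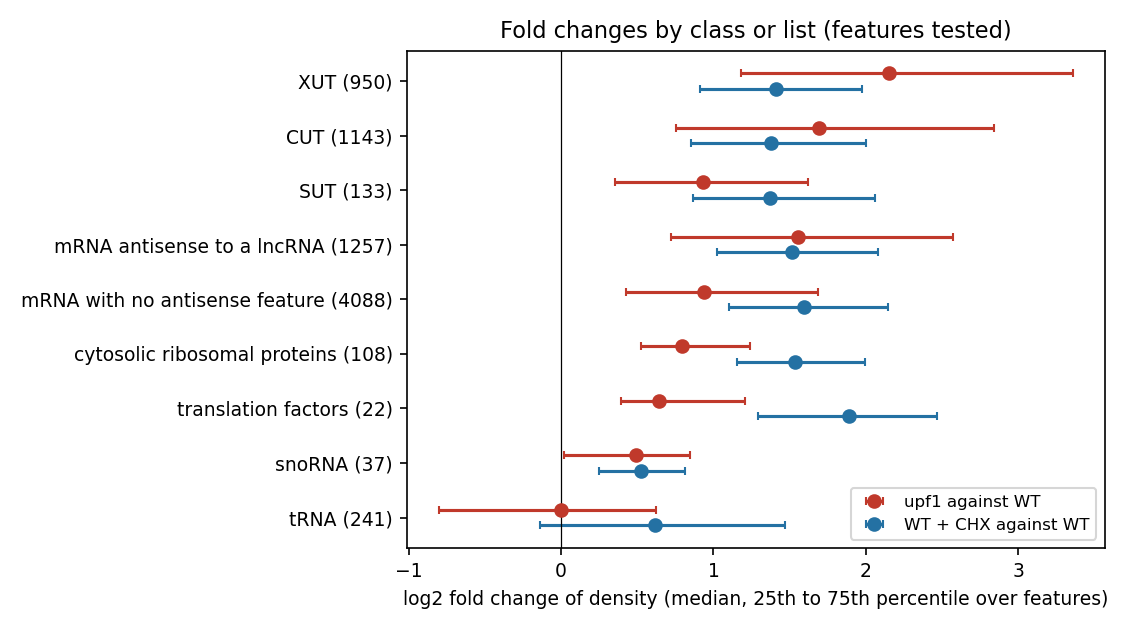
Median log2 fold change of density (points) with the 25th to 75th percentile over features (bars) for classes and lists, in upf1 against WT and WT CHX against WT, n = 2 libraries per group. XUTs lie at 2.15 in upf1 and 1.41 with CHX and translation factors at 0.64 and 1.89. With mRNA-median scaling XUTs (-0.34) and ribosomal proteins (-0.21) turn negative with CHX, as do translation factors (-0.58) and ribosomal proteins (-0.43) in upf1.

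Many features were called both with UPF1 loss and with CHX. 4122 features were higher in both. Independent lists of the same sizes would share 3508, which leaves out the shared WT libraries, and simulated libraries without any effect, where calls are rare, shared 0, so neither count is a measure of what the shared controls add. Fold changes correlated across features at 0.284, and at 0.165 and 0.174 with a different WT library as the control of each comparison. Simulations without any effect gave 0.501, a value that sharing the WT controls fixes in advance, so it is no benchmark for the 0.284. The covariance of the fold changes was 0.359, against 0.0873 from the shared controls alone, and 0.231 and 0.241 with the controls split.

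Compared directly, CHX-treated cells had fewer small RNAs from XUTs and more from mRNAs of the translation machinery than upf1 cells. 456 of 950 XUTs were lower and 84 higher in WT CHX than in upf1 (median log2 fold change -0.76; camera adjusted p = 4.13e-13, and adjusted p = 0.263 with an estimated correlation), as were 380 of 1143 CUTs, with 148 higher (median -0.29; camera adjusted p = 6.32e-05, and adjusted p = 0.305 with an estimated correlation). The 3 XUTs and the CUT at the start of chromosome 9 (4819 to 6729, plus strand) showed it most: XUT0919 had a density of 8.47 ± 0.205 in upf1, 0.140 ± 0.0509 in WT CHX and 0.0723 ± 0.00200 in WT, a 60.5-fold difference in density between upf1 and WT CHX (log2 -5.95, SE 0.23, limma adjusted p = 8.19e-06). XUT0920, XUT0921 and CUT1198, which share reads with it or lie beside it, were 55.4-fold, 43.3-fold and 49.3-fold lower, and the mRNAs on the other strand, NCAS_0I00100 and NCAS_0I00110, 50.1-fold and 43.5-fold lower. XUT0176 on chromosome 1 was 4.59-fold lower and the dense XUT0859 2.39-fold lower.

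On the other side, 13 of 22 translation factors were higher with CHX than in upf1 (median 1.33; camera adjusted p = 0.00363), as were 52 of 108 ribosomal protein genes (median 0.73; camera adjusted p = 3.43e-06), 9 of 14 glycolysis genes (median 0.66; camera adjusted p = 0.00427) and 1569 of 5361 mRNAs, with 837 lower (median 0.47, or -0.06 with mRNA-median scaling; camera adjusted p = 2.58e-08). With an estimated correlation these gave adjusted p = 0.263 for translation factors, ribosomal proteins and mRNAs and adjusted p = 0.305 for glycolysis, and no list of this comparison kept its call. With mRNA-median scaling the medians shrank to 0.80 for translation factors, 0.21 for ribosomal proteins and 0.14 for glycolysis. Those of XUTs and CUTs became more negative, at -1.29 and -0.82. TSR1, a factor of small ribosomal subunit assembly, was higher by a log2 of 4.51 (SE 0.28), TIF4632 and TIF4631, both eIF4G, by 3.07 (SE 0.53) and 2.45 (SE 0.32), RPL23A by 2.34 (SE 0.29) and PFK1 by 2.21 (SE 0.28). DHH1 was higher by 3.36 (SE 0.33) and XRN1 by 2.15 (SE 0.38), among 7 of 22 RNA decay genes (median 0.59). Single members went the other way: RPL28 was lower by a log2 of -1.30 (SE 0.18), and of the heat shock genes, 3 higher and 2 lower of 10, HSP60 was higher (1.66, SE 0.30) and HSP10 lower (-1.11, SE 0.21). XUT0122, antisense to the chaperonin gene CCT3, had 42 reads in WT CHX and 0 in upf1, at least 15.4-fold higher with the same floor over both upf1 libraries. Adjusted over the list alone, 13 translation factors, 52 ribosomal protein, 11 glycolysis, 7 RNA decay and 3 heat shock genes were higher, and 464 XUTs lower.

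In total 1904 of 7872 features were higher with CHX and 1717 lower, with a median log2 fold change of 0.24. With mRNA-median scaling 911 were higher and 2512 lower. The number higher was 1206 and 1167 without upf1 replicates 1 and 2, and 877 and 1224 without WT CHX replicates 1 and 2, and summed mRNA density was lower with CHX (0.683 ± 0.0517 times upf1) although the median mRNA was higher.

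In upf1 cells, loss of Dicer lowered the small RNAs of most tested features. Features that had risen in upf1 were not examined apart from the others. No untreated Dicer mutant with UPF1 was sequenced, so loss of the gain was not told apart from loss of small RNAs already present in WT. 889 of 927 XUTs were lower in dcr1 upf1 than in upf1 (median log2 fold change -5.70), as were 1023 of 1116 CUTs (-4.83), 109 of 128 SUTs (-3.94) and 4384 of 5249 mRNAs (-2.64, or 0.39 with mRNA-median scaling). XUT0620 (chromosome 5, 175427 to 177659, plus strand) fell from a density of 149 ± 11.2 to 0.210 ± 0.0426 (log2 -9.47, SE 0.20, limma adjusted p = 1.1e-09), and XUT0859 by a log2 of -9.99 (SE 0.18). CUT1261 fell by a log2 of -9.45 (SE 0.19) and XUT0058, the XUT that rose 155-fold in upf1, by -10.60 (SE 0.32). tRNA density did not follow: of 240 tRNAs 36 were lower and 17 higher (8 and 1 adjusted over the list alone), with a median of 0.00 (camera adjusted p = 5.32e-77 for a smaller fall than the rest, and adjusted p = 0.000198 with an estimated correlation). This 0.00 too can come from features without reads in either group.

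Genes of the lists lost their small RNAs to different degrees. DCP1, a subunit of the decapping enzyme, fell from a density of 0.589 ± 0.0254 to 0.00274 ± 0.00232 (log2 -7.25, SE 0.36), LSM6 by a log2 of -6.04 (SE 0.43) and NMD2 by -4.36 (SE 0.24). HHO1, the linker histone, fell by a log2 of -4.62 (SE 0.24), RPL18B by -4.54 (SE 0.24) and HSP104 by -3.43 (SE 0.42). UPF3 fell by a log2 of -2.70 (SE 0.32), which became 0.32 with mRNA-median scaling. In all, 14 of 22 RNA decay genes (median -2.29, or 0.73 with mRNA-median scaling), 18 of 22 translation factors (-1.56, or 1.47), 11 of 14 glycolysis genes (-1.65, or 1.38), 7 of 10 heat shock genes (-1.92, or 1.10), 4 of 8 histone genes (-1.50, or 1.53) and 61 of 108 ribosomal protein genes, 107 of them tested (-0.84, or 2.19), were lower. Of mRNAs antisense to a lncRNA 1167 of 1246 fell (median -4.06) and of those with no antisense feature 3201 of 3987 (-2.27, or 0.76). All 16 mRNAs antisense to another mRNA only fell (-5.98), as did 9 of the 10 XUTs with the DUT annotation (-7.29) and 23 of 37 snoRNAs (-1.58, or 1.44). Adjusted over the list alone the counts were 14, 18, 11, 7, 4 and 58 for the gene lists, in the same order, and 889 for XUTs.

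In total 6467 of 7704 features were lower and 22 higher, with a median log2 fold change of -3.11. With mRNA-median scaling 3004 were lower and 2479 higher, and with scaling on tRNA, rRNA and snoRNA 6474 and 25. Camera called 12 of 17 lists, of which tRNA alone held with an estimated correlation, and XUTs then had an adjusted p = 0.124. Of the 22 features that rose 17 were tRNAs, with 1 tRNA higher when adjusted over the list alone. The strongest was NCAS_0Ctrna1F on chromosome 3 (588442 to 588540), from a density of 0.928 ± 0.0372 to 7.99 ± 0.564 (log2 3.10, SE 0.19). Without dcr1 upf1 replicate 2 the number higher was 13, and HSP104 lost its call with mRNA-median scaling.

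In CHX-treated cells the loss of Dicer had the same direction. 870 of 927 XUTs were lower in dcr1 CHX than in WT CHX (median log2 fold change -4.52), 1009 of 1116 CUTs (-4.28), 117 of 128 SUTs (-4.31) and 4688 of 5249 mRNAs (-2.73, or 0.24 with mRNA-median scaling). XUT0525 and XUT0526, which overlap almost wholly on opposite strands of chromosome 3 (1160280 to 1161890), fell together. XUT0525 went from a density of 92.3 ± 6.61 to 0.222 ± 0.0175 (log2 -8.69, SE 0.17, limma adjusted p = 3.89e-09) and XUT0526 from 39.8 ± 5.17 to 0.0825 ± 0.000999 (log2 -8.88, SE 0.22). XUT0620 fell by a log2 of -8.42 (SE 0.20), XUT0859 by -7.95 (SE 0.18), CUT1261 by -8.65 (SE 0.19) and XUT0939, antisense to the permease genes BAP2 and TAT1, by -8.69 (SE 0.26). Of 240 tRNAs 41 were higher and 12 lower (12 and 5 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 5.73e-138, and adjusted p = 4.42e-05 with an estimated correlation).

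Again 9 of the 10 XUTs with the DUT annotation (median -6.48), all 16 mRNAs antisense to another mRNA only (-4.86), 1190 of 1246 mRNAs antisense to a lncRNA (-3.63) and 3482 of 3987 with no antisense feature (-2.50, or 0.47 with mRNA-median scaling) fell. So did 19 of 22 RNA decay genes (-2.48, or 0.50), 21 of 22 translation factors (-2.08, or 0.89), 13 of 14 glycolysis genes (-2.19, or 0.78), 8 of 10 heat shock genes (-1.55, or 1.43), 82 of 107 ribosomal protein genes (-1.46, or 1.51), 3 of 8 histone genes (-0.55, or 2.43) and 20 of 37 snoRNAs (-1.01, or 1.96). DCP1 fell by a log2 of -6.34 (SE 0.36), HHO1 by -5.17 (SE 0.24), EDC3 by -5.02 (SE 0.27), RPL18B by -4.89 (SE 0.24), NMD2 by -4.56 (SE 0.24), GCD10, a subunit of a tRNA methyltransferase, by -4.47 (SE 0.28) and DHH1 by -4.27 (SE 0.30). UPF3 fell by -1.77 (SE 0.32), which became 1.20 with mRNA-median scaling. Adjusted over the list alone, 19 RNA decay, 21 translation factor, 13 glycolysis, 8 heat shock, 81 ribosomal protein and 3 histone genes were lower, and 871 XUTs.

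In total 6719 of 7704 features were lower and 47 higher, with a median log2 fold change of -3.05, and 41 of the 47 were tRNAs, where 12 tRNAs were higher adjusted over the list alone. With mRNA-median scaling 2617 were lower and 2054 higher. Camera called 11 of 17 lists, of which tRNA alone held with an estimated correlation, and XUTs then had an adjusted p = 0.224.

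Few reads were left in the Dicer-deficient libraries at loci with many reads. Over the 88 lncRNA and mRNA features with at least 20000 reads in the 6 Dicer-proficient libraries together, a limit set after the data were seen, the dcr1 CHX libraries held a median of 0.146% of those pooled reads (0.117% to 0.208% from the 5th to the 95th percentile). As a share of the WT CHX reads alone the range was 0.369% to 4.86%. The dcr1 upf1 libraries held a median of 0.122% of the pooled reads (0.0993% to 0.190%). The narrow range depended on that limit: over the 289 features with at least 5000 pooled reads it was 0.106% to 0.827% for dcr1 CHX and 0.0854% to 0.818% for dcr1 upf1.

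**Figure D3:**
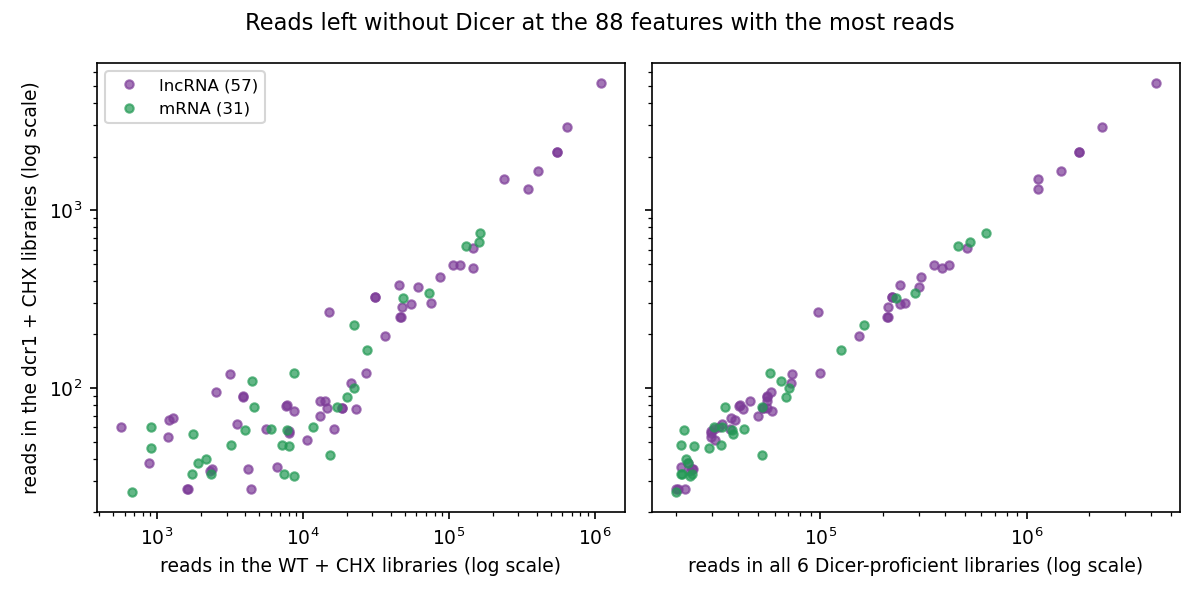
Reads in the dcr1 CHX libraries (log scale) at the 88 features with at least 20000 pooled reads, 57 lncRNAs and 31 mRNAs, some of which overlap, against the reads in the WT CHX libraries (left, log scale) and in all 6 Dicer-proficient libraries (right, log scale), each point being a feature summed over replicates. On the right the points keep close to a fixed share, 0.117% to 0.208% for the middle 90% of features, and on the left the share spreads from 0.369% to 4.86%.

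The contrast of Dicer loss in upf1 cells with Dicer loss in CHX cells largely restated the direct difference between WT CHX and upf1, since few reads were left without Dicer and the same libraries enter both. By limma, 1426 of 7704 had a more negative log2 fold change in upf1 cells and 417 a less negative one, with a median difference of -0.22. Of these, 1234 and 404 differed in the same direction between WT CHX and upf1. XUTs leaned to the larger fall in upf1 cells (360 against 28 of 927, median difference -1.08; camera adjusted p = 2.8e-08), as did CUTs (288 against 41 of 1116, -0.65; camera adjusted p = 0.0207), and ribosomal protein genes to the smaller one (15 against 2 of 107, 0.47; camera adjusted p = 2.96e-07). With an estimated correlation these gave adjusted p = 0.230 each. XUT0919, XUT0921 and CUT1198 on chromosome 9 had differences of -7.51 (SE 0.45), -6.23 (SE 0.45) and -6.43 (SE 0.43), and XUT0058 one of -5.94 (SE 0.45, limma adjusted p = 6.96e-05). DHH1 (2.78, SE 0.43) and RPL23A (1.84, SE 0.36), which were higher with CHX than in upf1, had differences of the other sign.

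Few reads in the Dicer-deficient libraries make the size of these differences depend on the pseudocount, and with one 10 times larger or smaller the counts became 1887 and 1445 or 879 and 94. The number with a smaller fall in upf1 cells was 276 without upf1 replicate 1, 220 and 217 without dcr1 upf1 replicates 1 and 2, and 176 without WT CHX replicate 1.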

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

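The tests of reads left without Dicer, those of the rise of mRNA strands with CHX and the nested-pair test of strand were chosen only after the results were seen, while the tests of read depth and of joint change on both strands were not.

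For the features and lists in this paragraph, what drew attention is a call in the interaction test, which sets Dicer loss in upf1 cells against Dicer loss in CHX-treated cells. With few reads left without Dicer it largely restates the direct difference between WT CHX and upf1, which had the same direction for 404 and 1234 of the features called. 417 features had a higher and 1426 a lower Dicer-loss value in upf1 cells. Among lists, the median log2 difference was -1.08 for XUTs, -0.65 for CUTs, -0.47 for mRNAs antisense to a lncRNA, -0.046 for all mRNAs, 0.064 for mRNAs with no antisense feature, 0.47 for ribosomal proteins, 0.48 for translation factors and 0.71 for glycolysis. The calls of all 8 lists were lost with an estimated correlation, with an adjusted p = 0.230 for 7 of them and adjusted p = 0.389 for mRNAs antisense to a lncRNA. Among dense lncRNAs, the difference was -1.05 for XUT0620 and -2.03 for XUT0859. Among the features with the largest changes it was -5.94 for XUT0058, -7.51 for XUT0919, -6.40 for XUT0920, -6.23 for XUT0921 and -6.43 for CUT1198. It was 2.78 for DHH1, 1.84 for RPL23A and 2.12 for the tRNA NCAS_0Ctrna1F. For XUT0122, with 0 reads in upf1 and in both Dicer-deficient groups, the fitted 5.75 depends on the pseudocount and is no bound.

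Reads remained in both Dicer-deficient groups at the 88 features with the most small RNAs, where dcr1 CHX held 0.117% to 0.208% of the pooled Dicer-proficient reads, a range that widened to 0.106% to 0.827% over the 289 features with at least 5000 pooled reads. Dicer-independent RNA in proportion to the small RNAs of the same background is argued against: the slope of the log2 ratio of dcr1 upf1 to dcr1 CHX reads on that of upf1 to WT CHX reads was -0.0644 (SE 0.0181) over the 88 features and -0.0539 (SE 0.0237) over 55 that do not overlap on either strand, where 0.5 or more was required. Reads carried over from other libraries stay open as a candidate explanation, since the upf1 libraries, which share neither strain nor treatment with dcr1 CHX, predicted its log2 reads. XUT0058 kept 37 and 66 reads in the groups whose Dicer-proficient counterparts held 37017 and 1212. The features were chosen on pooled reads that include upf1. For dcr1 CHX the coefficient of upf1 was 0.698 (SE 0.0268), or 0.704 (SE 0.0339) over the 55, beside 0.262 for WT CHX (in dcr1 upf1 its own background led, with 0.635 for upf1 beside 0.326 for WT CHX). Over the 289 features the order turned round, with a coefficient of 0.294 (SE 0.0612) for upf1 beside 0.443 for WT CHX, or 0.195 (SE 0.0878) beside 0.522 over 183 that do not overlap, while the slope was 0.0113, and Dicer-independent RNA at a level unrelated to the background was not tested. If carry-over is real, Dicer-loss values and interaction values at loci such as XUT0058 may be set partly by it.

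With CHX the strands of mRNAs rose with a median log2 fold change of 1.57. Spike-in scaling of the CHX libraries as the whole cause is argued against, since scaling on tRNA, rRNA and snoRNA left a median of 1.24 where a value below 0.5 was required, a test that takes those RNAs as a stable reference. Fragments of mRNA made without Dicer are argued against as the main cause, since over the 4363 mRNAs that rose the dcr1 CHX density was a median of 9.57% of the rise (25th to 75th percentile 3.81% to 23.0%), where 50% or more was required. A part played by scaling stays open, because with that reference 4794 rather than 6070 features were higher and 41 rather than 13 lower. An effect of the translation block itself, the biological explanation that the design names, stays open as untested, since no other translation block was sequenced.

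In upf1 cells, mRNAs with an antisense lncRNA rose more than those without, by 0.616 in median log2 fold change. Counting without regard to strand is argued against: in 16.2% of 390 pairs with a lncRNA wholly inside the interval of an mRNA the lncRNA had more upf1 reads than the mRNA, where strand-blind counting allows at most 5%. An earlier test of strand, the median absolute log2 ratio of the strands of 153 near-identical pairs (0.399), had not decided the question. Read depth cannot be told apart as an explanation, since within 10 bins of mean density the difference shrank to 0.252, which lies within its error of the 0.2 set as the limit, and that density includes the upf1 libraries themselves. A joint response of both strands of a locus is a hypothesis that the pairs allow, with both strands higher in 66.2% of pairs against at most 61.9% in redrawn pairs, and it may account for part of the difference. The redrawing did not match the density of the mRNA, which may contribute to that excess.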

How the results depend on the processing

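There were 2 libraries per group. The Dicer-deficient libraries had fewer reads than WT and a larger squared variation between replicates, used as the dispersion in the simulations (0.0306 and 0.0476, against 0.00896). Counting noise was not removed from that value, so it is not a spread separate from read number. The parts of read number and spread in the low recovery were not told apart. Leaving out a library leaves a group with 1 sample that is assumed to vary like the others. Of 109 results for a named feature in a comparison, 85 kept their direction and their call under every setting run, 21 lost the call under at least 1 setting, 6 reversed and 1 (NAM7) gained it. Causes of changes were not tested unless stated. The voom fit, the fit with every annotation entry, the fit without shared intervals and the carry-over tests on features that do not overlap were chosen after seeing the data.

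With mRNA-median scaling, which removes any change common to mRNAs by construction, 2114 features were higher and 1026 lower in upf1 than in WT, 722 and 1215 in WT CHX than in WT, 2479 and 3004 in dcr1 upf1 than in upf1, and 2054 and 2617 in dcr1 CHX than in WT CHX, and 911 were higher in WT CHX than in upf1. It reversed XUT0620 (-0.41) and CUT1261 (-0.55) in upf1, XUT0859 (-1.24) and CUT1261 (-1.19) with CHX, and UPF3 in dcr1 upf1 (0.32) and dcr1 CHX (1.20). With scaling on tRNA, rRNA and snoRNA the number lower was 82 in upf1 and 41 with CHX, and the number higher in dcr1 CHX 26. The number higher with that scaling was 3787 rather than 4549 in upf1 and 4794 rather than 6070 with CHX.

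A filter at 10 times the pseudocount, which tests fewer features, gave 8 lower with CHX against WT, 1158 higher with CHX against upf1, 3659 and 3665 lower without Dicer in upf1 and CHX cells, and 195 higher in the interaction. Requiring a 2-fold change left 12 higher in dcr1 upf1 and 1 feature lower in both upf1 and CHX. Keeping every annotation entry, with its repeated tRNA intervals, gave 72 higher in dcr1 CHX. For the interaction, the larger pseudocount gave 1445 higher, the smaller one 94 higher and 879 lower, and voom on recovered reads 124 higher. Leaving out 1 library at a time gave 22 to 35 features lower with CHX against WT, 877 to 1224 higher with CHX against upf1, 13 to 28 higher in dcr1 upf1 and 176 to 400 higher in the interaction, and moved no other count of calls by over 1.5 times.

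Class ratios depended on the summary, and the cause was not tested. Leaving out the 10 densest features left SUT, snoRNA and tRNA unchanged. As the median over features, the ratio of upf1 to WT was 5.61 for XUT, 3.98 for CUT, 1.83 for SUT and, reversed, 0.990 for tRNA. That of WT CHX to WT was 3.36 for XUT, 3.42 for CUT, 3.24 for SUT, 3.92 for mRNA, 1.95 for snoRNA and 2.003 for tRNA. That of WT CHX to upf1 was 0.599 for XUT, 0.859 for CUT, 1.78 for SUT and 1.52 for mRNA (both reversed), 1.55 for snoRNA and 2.02 for tRNA. That of dcr1 upf1 to upf1 was 0.0546 for mRNA and 0.852 for tRNA (reversed), and that of dcr1 CHX to WT CHX 0.0144 for SUT, 0.0814 for mRNA, 0.301 for snoRNA and 1.19 for tRNA. Without the 10 densest features, the ratios for XUT, CUT and mRNA were 2.83, 4.53 and 4.45 in upf1 against WT, 1.54, 2.04 and 2.502 with CHX against WT, and 0.546, 0.451 and 0.562 with CHX against upf1. They were 0.00188 for XUT and 0.0279 for mRNA in dcr1 upf1, and 0.00684, 0.0111 and 0.0738 for XUT, CUT and mRNA in dcr1 CHX.

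With a pseudocount 10 times larger, camera also called CUTs (adjusted p = 0.0387) and mRNAs (0.0234) in upf1 against WT, mRNAs antisense to a lncRNA with CHX against upf1 (0.0484) and translation factors in dcr1 upf1 (0.0435). It no longer called RNA decay in dcr1 upf1 (0.0964), CUTs (0.123) and mRNAs with no antisense feature (0.112) in dcr1 CHX, or mRNAs antisense to a lncRNA in the interaction (0.0562). Camera with an estimated correlation called 1 list each for upf1 against WT, WT CHX against WT and both Dicer comparisons, and 0 for WT CHX against upf1 and the interaction. With split WT controls the correlation of the upf1 and CHX responses was 0.165 or 0.174 and the covariance 0.231 or 0.241.

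Deviations of same-numbered libraries correlated between -0.0311 and 0.0203, so no deviation shared by replicate number was seen. This does not decide whether same-numbered samples were paired. With the replicate number as a block, the counts higher and lower were 4472 and 57 in upf1 against WT, 6025 and 15 with CHX against WT, 1827 and 1687 with CHX against upf1, 22 and 6445 in dcr1 upf1, 49 and 6707 in dcr1 CHX and 346 and 1356 in the interaction, all within 1.5 times of the fit without it. Camera then also called histones in upf1 against WT (adjusted p = 0.0484, against 0.0612 without the block), mRNAs antisense to a lncRNA (0.0498) and tRNAs (0.0486) with CHX against upf1, and SUTs in the interaction (0.0470).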

Other observations

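The summary by density and the choice of the single tRNA locus were made only after the results were seen, and the tests of chromosome ends were set out before their values were computed.

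In 5 equal bins of mean density over WT, upf1 and WT CHX, from the sparsest to the densest, the median log2 fold change was 0.58, 0.91, 1.18, 1.67 and 2.30 in upf1 against WT and 1.31, 1.56, 1.64, 1.64 and 1.40 with CHX against WT. A feature that rises moves into a denser bin by its own rise, and sparse features lose part of their change to the pseudocount, so the trend in upf1 is partly set by the binning. The 10 features with the highest mean density over all libraries, at the far end of the densest bin, had a median log2 fold change of 0.68 in upf1 against WT and 0.43 with CHX, where the medians over all tested features were 1.19 and 1.502. That mean includes the upf1 and CHX libraries, so features that rise are favoured in the choice.

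A tRNA locus on chromosome 3, NCAS_0Ctrna1F (588442 to 588540), had a density of 0.267 ± 0.0178 in WT, 0.928 ± 0.0372 in upf1 and 5.19 ± 1.16 in WT CHX (SD, n = 2 each), and 7.99 ± 0.564 in dcr1 upf1 and 10.2 ± 0.686 in dcr1 CHX. It rested on 101 reads in WT and 4531 in dcr1 upf1, and other tRNA loci with the same sequence, if any, share its reads to an unknown extent.

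Several of the largest rises in upf1 lie near the first or last annotated feature of a chromosome, among them CUT0912 on chromosome 6 (3941 to 4686), CUT1109 on chromosome 8 (9256 to 10139), NCAS_0J00110 on chromosome 10 (2167 to 3219) and the XUT0919 to XUT0921 cluster on chromosome 9. The hypothesis that chromosome ends respond more to UPF1 loss was tested with the 267 tested mRNAs and lncRNAs within 20 kb of the outermost annotated features of the 10 chromosomes, a set that contains the loci that prompted it. Their median log2 fold change in upf1 was 2.33, above all of 10000 random lists matched on class and density (median 1.48, highest 1.89), and 193 were called higher. The density used for matching includes the upf1 and CHX libraries. The random lists were drawn feature by feature over the genome, whereas features near ends include neighbours that share reads or change together. The range of the random lists may therefore be too narrow, here and in the comparisons below, and the loci that prompted the hypothesis were not left out. The same hypothesis for CHX came out negative, with a median of 1.23 against 1.46 in matched lists, below 1.36, their 2.5th percentile. In the direct comparison of WT CHX with upf1 the median was -1.22, against -0.06 in matched lists, with 151 features lower and 28 higher. How reads that map to several chromosome ends were treated is not given in the sources used here, so a single responding repeat counted at several ends may contribute to the 2.33, and no test here decides that.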
